A study of Mus musculus with 4 samples.

How the data were processed

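Pancreas RNA from Cyp11a1 knockout and wild-type mouse embryos late in gestation was compared on 4 two-colour Agilent arrays, each holding 1 knockout and 1 wild-type extract. Per the labels, the knockout extract carried the red dye and the wild-type extract the green dye on all 4 arrays, so no array had the dyes swapped. Per the labels, 20 µg of total RNA were reverse transcribed from anchored oligo(dT) with amino-allyl dUTP and coupled to the dyes afterwards. The labels call the 4 arrays biological replicates. They also give each extract a code, and the meaning of the codes is not stated. Both extracts of array 3 and the wild-type extract of array 1 have codes that begin with BF. The knockout extracts of arrays 1 and 2 have codes that begin with BB. The tests below treat the 4 arrays as independent, and a shared origin of extracts was not tested. Whether an extract came from 1 embryo or several, and whether the 2 extracts of an array came from littermates, is not given in the sources used here, and the sex of the embryos is not given either.

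The authors scanned the arrays and extracted the spots with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. Per the file headers, each array holds for every spot its median red and green signal and local background as intensity on a linear scale, processed signals after Feature Extraction's own background and dye correction, also as intensity, and the log10 ratio of red over green. The log10 ratio equalled the ratio of the processed signals within 0.001 for 90.7% of spots. Per the file headers, each spot is also marked as outlier, saturated or well above background. The planned test named mean signals, and median signals, which the files list, were used in their place.

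Median signals were background-corrected with normexp (offset 50) and normalised within each array by loess, with control spots and spots marked as non-uniform at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as non-uniform (597 to 979 per array) were then left out, and spots of one probe were averaged. No spot was saturated. Of 41174 different probes, 25097 (61.0%) were given a current symbol by matching the accession of the array design, without its version, to RefSeq transcripts in a gene table of assembly GRCm38.p6, and the others stayed unnamed. The array files name an older build, so no coordinate of that table was used. A probe was tested if it was well above background in the red channel on at least 3 of the 4 arrays, or in the green channel on at least 3. Each gene was represented by its probe with the highest mean brightness, which left 15523 genes, 600 of them with values on 3 arrays.

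The log2 ratio of knockout over wild type was fitted with limma (lmFit and eBayes) against 0, so that the pairing of the 2 extracts on an array is inside each value. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Values are given as mean ± SE from this fit over 4 arrays unless another n is stated. All arrays were on 1 slide with 1 scan, so no batch of slides or scans could be compared. Because knockout and red dye coincide, a gene-specific dye effect cannot be told apart from genotype in any comparison. Spike-in controls, per the file headers, gave a slope of 0.67 to 0.73 for observed against expected log ratios.

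The main test, the alternatives below unless said otherwise, the named-gene rule and 32 gene lists were chosen before the data were examined. The lists were tested with camera at a preset correlation of 0.01, adjusted over the lists. For these tests a missing value was replaced by the gene's mean over the other arrays. Alternatives were camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes. The rule for named genes took Cyp11a1, then the 10 largest increases and 10 largest decreases among genes past the threshold with 1 sign on all 4 arrays, leaving out names that are only a clone or accession. It also took up to 4 members of each list with the smallest p-values, and every measured islet hormone, sex-linked gene and steroid receptor. Members of those lists named beyond this rule were chosen after their values were seen: Mcm6, Gamt, Ier2, Mt1, Atf3, Atf4, Pdia6, Sgk1, Tsc22d3, Cpa1, Cel, Cpb1, Cela1, Pnliprp2, Try5, Col6a1, Hadhb, Acadvl, Chgb, Alb and Ahsg. They were run under the same alternatives. A few genes that the rule takes are not reported here by name.

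Other settings were no background correction, Feature Extraction's processed signals with loess, its log ratio column, median centring in place of loess, scaling between arrays, no filter or a strict filter on dim probes, the mean of a gene's probes, every probe on its own, single channels without the array as a block, eBayes with trend and robust, array weights, and leaving out each replicate. Leaving out spots marked as population outliers, and leaving out replicates 1 and 3 together, were added after the data had been seen. The procedure was tested on simulated signals for this comparison, with 15523 genes run, a dye curve on each array and spot noise drawn independently. Of 61 tested genes per size, 67.2% were recovered at a fold of 1.3, 82.0% at 1.5 and 95.1% at 2, and 4.62% of the calls were unchanged genes. No dye effect of single probes or transcripts was simulated, nor a difference in sex or in carried-over tissue. These shares therefore need not hold for the calls in the real arrays. With 4 arrays, the number of arrays limits the precision. A total of 10233 unnamed probes passed the filter on brightness, and 818 of them passed the threshold when every probe was tested on its own. They were not used in the gene comparison.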

Results

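The series measured gene expression in whole pancreas of mouse embryos late in gestation, and compared embryos lacking Cyp11a1 with wild-type embryos. Cyp11a1 encodes the mitochondrial enzyme that converts cholesterol to pregnenolone, the first step of steroid hormone synthesis. Each of 4 arrays compared 1 knockout with 1 wild-type extract. The median spot signal was 304 to 467 in the knockout channel and 163 to 224 in the wild-type channel, and 78.2% to 85.1% of spots were well above background in a channel.

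Cyp11a1 itself gave a log2 ratio of -0.16 ± 0.070 (SE, n = 4 arrays, limma adjusted p = 0.164) on its brighter probe (A_51_P309727), with -0.19, -0.40, 0.013 and -0.072 on arrays 1 to 4, and did not pass the test. This probe was well above background in both channels on all 4 arrays. The second probe (A_51_P309733) was well above background on 0 arrays in knockout and on 1 in wild type, so no fold is given for it. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so neither probe checks the genotype labels.

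The largest increase in knockout pancreas was in Serpina6. It encodes corticosteroid-binding globulin and rose by 1.54 ± 0.21 (log2, SE, or 2.92-fold). Gc, the vitamin D binding protein, rose by 1.28 ± 0.11, and Vtn, vitronectin, by 1.20 ± 0.099. Mt2, a metallothionein that glucocorticoids and metals induce, rose by 1.20 ± 0.17. Rplp1 (1.09 ± 0.087), Spink1 (1.04 ± 0.076), the peroxisomal oxidase gene Pipox (0.95 ± 0.051), Rps24 (0.93 ± 0.062), Pnliprp1 (0.92 ± 0.096) and Cpn1 (0.91 ± 0.054) completed the 10 largest increases. The largest decreases were in Tmed11, of a family of vesicle transport proteins in the early secretory pathway, which fell by 2.30 ± 0.20, and in Chac1, a glutathione-degrading enzyme induced by Atf4, which fell by 2.14 ± 0.11.

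Gp2, the main glycoprotein of zymogen granule membranes, fell by 1.52 ± 0.10, and Dmbt1, a secreted glycoprotein, fell by 1.37 ± 0.15. Hsd17b13, a lipid droplet protein, fell by 1.11 ± 0.12 and Msmo1, a sterol oxidase of cholesterol synthesis, fell by 1.08 ± 0.12. The decreases in Sugct (-1.11 ± 0.14), Srgap3 (-0.998 ± 0.16), Lyzl6 (-0.98 ± 0.10) and Nup214 (-0.98 ± 0.12) rest on 1 probe each. The other tested probe of these genes gave 0.043, 0.098, -0.11 and 0.16, and without replicate 4 the other probe of Sugct became the brighter one, which gave 0.075 (adjusted p = 0.474). All 20 genes had 1 sign on all 4 arrays and passed the threshold because the rule required both, with limma adjusted p between 9.2e-04 and 0.0097 (Srgap3). With eBayes trend and robust, Serpina6, Mt2 and Srgap3 did not pass (limma adjusted p = 0.065, 0.064 and 0.069).

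**Figure D1:**
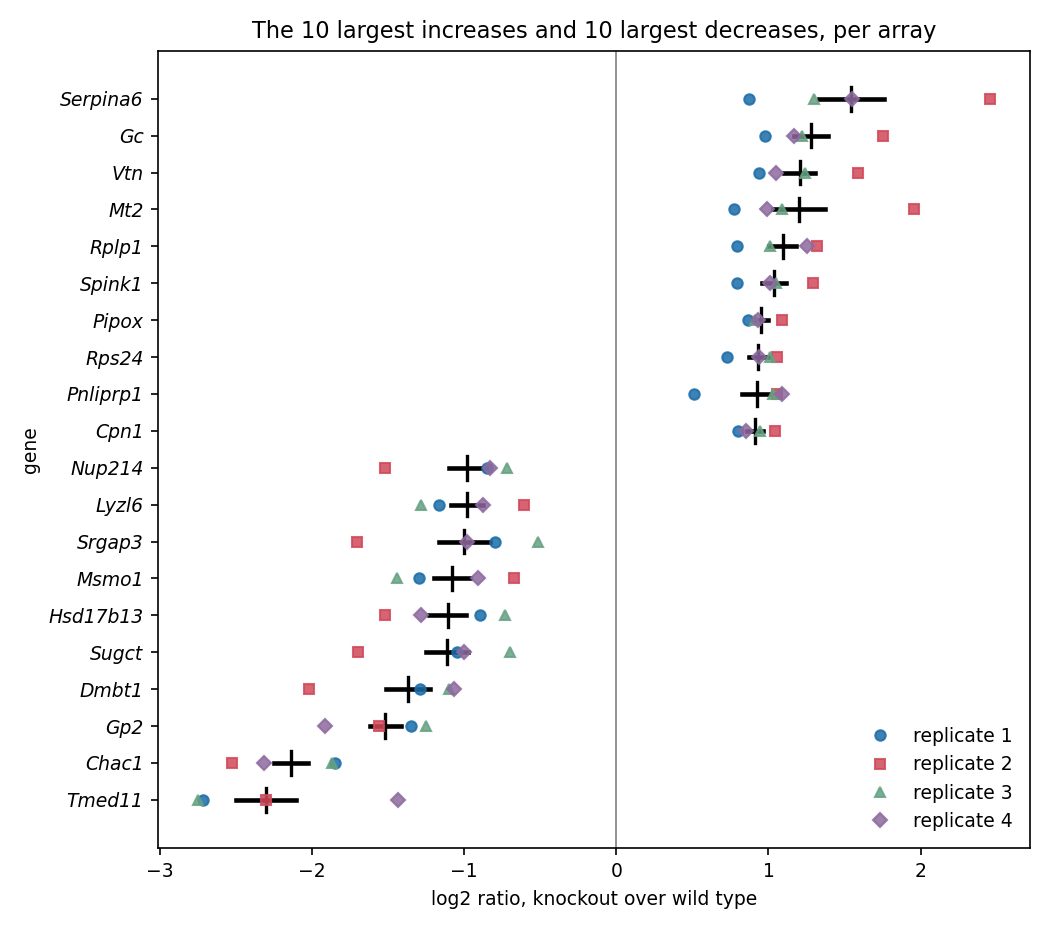
Log2 ratios of knockout over wild type (x axis) for the 10 largest increases and 10 largest decreases (y axis, genes), with 1 point per array, a vertical tick at the mean and a horizontal bar of ± 1 SE. All points of a gene lie on one side of 0, which the rule for choosing these genes required, and the means run from -2.30 for Tmed11 to 1.54 for Serpina6.

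In all, 2260 of 15523 genes (14.6%) passed the threshold, 1467 higher and 793 lower in knockout, and 4777 had an unadjusted p under 0.05. Of the 2214 called genes measured on 4 arrays, 2208 had 1 sign throughout. The median size of the change among called genes was 0.27 on the log2 scale. A fold of 1.5 or more was reached by 69 called genes that were higher and 81 that were lower, and a fold of 2 or more by 6 and 7. Log2 ratios correlated across genes between arrays with Pearson's r of 0.31 to 0.60, a description only, since genes are not independent replicates. Arrays 1 and 3 (0.60) and arrays 2 and 4 (0.59) correlated most, and the other pairs reached at most 0.43. Arrays 1 and 3 share code letters of extracts, as do arrays 1 and 2 (0.43), whereas arrays 2 and 4 share none. Arrays 1 and 3 were also alike in Xist (-3.91 and -4.22), whereas arrays 2 and 4 differed in it (-0.28 and 3.46). Whether a shared origin of extracts or the sex of the embryos raised or lowered a correlation was not tested. Fewer genes passed without replicate 1 (1163), replicate 3 (963) or replicate 4 (1044), and 91 passed when the array was ignored as a block. With median centring in place of loess 11921 genes passed, 79.4% of them higher against 64.9% with loess, and the median of all genes was 0.26 against 0.013. Unless given relative to that median, values and counts with median centring are taken against 0 and carry this shift. A value above 0 can thus lie below the median of all genes. Relative to that median, 103 of the 107 named genes past the threshold kept their loess sign.

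Genes of cholesterol synthesis and uptake fell in knockout pancreas, but with median centring their median was 0.018, or -0.24 relative to the median of all genes. With loess the list median was -0.32 (camera adjusted p = 2.5e-13; adjusted p = 0.341 with an estimated correlation). Of 25 measured members, 18 fell, 0 rose and 7 did not pass (21 fell adjusted over the list alone). Hmgcs1, which makes the precursor of mevalonate, fell by 0.93 ± 0.095, Cyp51, lanosterol demethylase, fell by 0.74 ± 0.069, and Hsd17b7, a sterol ketoreductase, fell by 0.56 ± 0.054. The other tested probes of Cyp51 gave -0.71 and -0.27.

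Ribosomal protein genes rose almost throughout. Of 34 measured, 33 rose and 0 fell (34 rose adjusted over the list alone), with a median of 0.53 (camera adjusted p = 1.0e-25; adjusted p = 0.391 with an estimated correlation). Besides Rplp1 and Rps24, Rpl23 rose by 0.87 ± 0.069 and Rpl10 by 0.75 ± 0.065. The other tested probe of Rpl23 gave 0.28. These genes have many processed pseudogenes, so their probes can also bind transcripts of other copies.

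Cell cycle genes rose as a group, with a median of 0.24 (camera adjusted p = 3.4e-09; adjusted p = 0.341 with an estimated correlation). Of 33 measured members 20 were higher, 1 lower and 12 not past the threshold (25 and 1 adjusted over the list alone). Mki67, the proliferation antigen, rose by 0.60 ± 0.043, Ccna2, cyclin A2, by 0.50 ± 0.046, and Tyms, thymidylate synthase, by 0.46 ± 0.045. Mcm5, a subunit of the replicative helicase, went the other way at -0.76 ± 0.092, whereas Mcm6 of the same complex rose by 0.43 ± 0.057.

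Of 33 respiratory chain genes, 13 rose and 0 fell (20 and 0 adjusted over the list alone). Atp5o and Atp5j, subunits of ATP synthase, rose by 0.51 ± 0.063 and 0.38 ± 0.058, and Ndufa4 rose by 0.40 ± 0.061. The list median of 0.17 passed (camera adjusted p = 7.9e-08; adjusted p = 0.738 with an estimated correlation). Of 24 genes of fatty acid oxidation, 5 rose and 1 fell (6 and 1 adjusted over the list alone), and the list did not pass (median 0.064, camera adjusted p = 0.20). Acaa2 (0.36 ± 0.056), Cpt2 (0.33 ± 0.049) and Hadha (0.31 ± 0.049), which act in mitochondrial beta oxidation, rose. Hadhb was at 0.23 ± 0.054 (adjusted p = 0.070 to 0.10 without replicate 2, 3 or 4) and Acadvl at 0.22 ± 0.046 (adjusted p = 0.091 to 0.092 without replicate 3 or 4). Cd36, a fatty acid transporter, was lower at -0.26 ± 0.046 with loess (adjusted p = 0.053 without replicate 3 or 4) but at 0.069 with median centring.

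Of 27 measured genes of amino acid uptake, synthesis and breakdown, 11 fell and 1 rose (14 and 2 adjusted over the list alone), whereas with median centring 6 fell and 12 rose. Psat1, of serine synthesis, fell by 0.53 ± 0.056, and the transporter genes Slc38a2, Slc7a5 and Slc1a4 were lower at -0.46 ± 0.053, -0.44 ± 0.057 and -0.43 ± 0.064. With median centring Slc38a2 and Slc7a5 did not pass (-0.0035 and -0.11). Gamt, of creatine synthesis, was the member that rose, by 0.33 ± 0.059 (adjusted p = 0.054 without replicate 4). The list median was -0.12 (camera adjusted p = 2.5e-05; adjusted p = 0.341 with an estimated correlation), and 0.091 with median centring, or -0.16 relative to the median of all genes.

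Of 22 measured genes of the unfolded protein response, 6 were higher and 4 lower (10 and 4 adjusted over the list alone), whereas with median centring 18 were higher and 3 lower, with a median of 0.65. Hsp90b1, a chaperone of the endoplasmic reticulum, rose by 0.37 ± 0.069 (n = 3 arrays), and the folding enzymes Pdia4 and Pdia6 were higher at 0.31 ± 0.061 (adjusted p = 0.068 without replicate 4) and 0.36 ± 0.073 (adjusted p = 0.062 without replicate 4). The other tested probes of Pdia6 gave 0.061 and 0.34. Besides Chac1, Trib3 fell by 0.33 ± 0.055, and Atf3 was lower at -0.37 ± 0.085 (adjusted p = 0.064 to 0.089 without replicate 1, 2 or 4). Atf4, a transcription factor of the integrated stress response, was lower at -0.35 ± 0.074 (adjusted p = 0.071 to 0.079 without replicate 3 or 4) but at 0.10 with median centring. The list did not pass (median 0.16, mean 0.0013, camera adjusted p = 0.334).

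Of 36 measured genes that glucocorticoids induce in many tissues, 6 fell and 2 rose (8 and 3 adjusted over the list alone). Klf9, a transcription factor, fell by 0.57 ± 0.062, Fkbp5, a co-chaperone of the glucocorticoid receptor, fell by 0.55 ± 0.064, Cdkn1a fell by 0.40 ± 0.047 and Sgk1, a kinase, fell by 0.41 ± 0.059. With median centring Fkbp5 and Sgk1 did not pass (-0.15 and -0.022). The other tested probes gave -1.25 for Klf9 and -0.71 and -0.64 for Fkbp5. The members that rose were the metallothionein genes Mt2 and Mt1 (0.80 ± 0.21, adjusted p = 0.063 to 0.104 without replicate 3 or 4, and 0.50 without replicate 2), and Tsc22d3, another common target, was at -0.10 ± 0.046 and did not pass. The list median was -0.074 (camera adjusted p = 0.0027; adjusted p = 0.341 with an estimated correlation), and 0.14 with median centring, or -0.11 relative to the median of all genes.

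Among 12 steroid receptors and their regulators, Fkbp4, a receptor co-chaperone, rose by 0.29 ± 0.045 and Ncoa3, a coactivator, was lower at -0.70 ± 0.079 (3 rose and 2 fell adjusted over the list alone). The other tested probes of Ncoa3 gave -0.029 and -0.039. Nr3c1, the glucocorticoid receptor, was at 0.19 ± 0.058 (limma adjusted p = 0.071), Esr1 at -0.011, Esr2 at -0.19 and Nr3c2 at 0.054, none past the threshold. Ncoa1 (0.17), Ncoa2 (0.099), Hsp90aa1 (0.081), Hsp90ab1 (0.084) and Ptges3 (0.024) did not pass either. Other tested probes gave 0.092, 0.093 and 0.016 for Nr3c1 and 0.19 and 0.27 for Nr3c2. They gave 0.080 and 0.025 for Ncoa2, 0.21 for Hsp90ab1 and -0.11 for Ptges3. None of these other probes passed when every probe was tested on its own. Without 1 replicate, Esr1 ranged from -0.038 to 0.019, Esr2 from -0.29 to -0.025, Nr3c2 from 0.014 to 0.091, Ncoa2 from 0.043 to 0.16, Hsp90aa1 from 0.036 to 0.12, Hsp90ab1 from 0.038 to 0.11 and Ptges3 from -0.030 to 0.061. The list did not pass (median 0.068, mean -0.011, test upwards, camera adjusted p = 0.694).

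Of 23 genes of steroid hormone synthesis and metabolism, 1 rose and 2 fell, also when adjusted over the list alone, whereas with median centring 8 rose and 8 fell (median -0.027 with loess, camera adjusted p = 0.447). Hsd11b1, which regenerates active glucocorticoid, was lower at -0.34 ± 0.051 with loess but at 0.079 with median centring. Hsd17b7 fell, and Cyp7b1 was higher at 0.21 ± 0.051 (adjusted p = 0.061 to 0.104 without replicate 1, 2, 3 or 4), and with median centring it did not pass (0.12).

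Acinar products changed in both directions. Of 31 measured, 8 rose and 10 fell (10 and 10 adjusted over the list alone), whereas with median centring 22 rose and 3 fell. Besides Spink1, a trypsin inhibitor, and Pnliprp1, a lipase relative, Tff2 rose by 0.65 ± 0.057, Cpa1, a carboxypeptidase, by 0.62 ± 0.092, and Cel, a lipase, by 0.66 ± 0.095. Besides Gp2 and Dmbt1, Cela1, an elastase, fell by 0.69 ± 0.12, Cpb1, a carboxypeptidase, was lower at -0.78 ± 0.17 (adjusted p = 0.052 to 0.055 without replicate 1 or 3), and Pnliprp2 was lower at -0.73 ± 0.14 (adjusted p = 0.051 to 0.054 without replicate 1 or 3). With median centring Cela1, Cpb1 and Pnliprp2 did not pass (-0.080, -0.20 and -0.21), nor did they with eBayes trend and robust (limma adjusted p = 0.063, 0.144 and 0.089). Try5, a trypsin with close paralogs and so an uncertain value, was lower at -0.56 ± 0.081 with loess but at 0.052 with median centring. The list did not pass (median 0.0078, mean -0.031, test downwards, camera adjusted p = 0.694).

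Of 11 acinar transcription factors and receptors, 2 rose and 1 fell, also when adjusted over the list alone (median 0.071, camera adjusted p = 0.453). Rbpjl, a subunit of the acinar PTF1 complex, rose by 0.40 ± 0.073, and Chrm3, a muscarinic receptor, fell by 0.89 ± 0.13. Foxa2, a transcription factor, was higher at 0.35 ± 0.065 (adjusted p = 0.0502 without replicate 4).

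None of 7 islet hormone genes passed the threshold in limma, also when adjusted over the list alone, and 1 had an unadjusted p under 0.05 (Sst). Ins1 was at 0.013 ± 0.052 and Ins2 at -0.025 ± 0.053, with unadjusted 95% intervals of -0.11 to 0.13 and -0.15 to 0.098. Gcg, glucagon, was at 0.036 ± 0.14. The others were Sst at 0.15 ± 0.057, Ghrl at -0.14 ± 0.066, Pyy at -0.071 ± 0.059 and Ppy, pancreatic polypeptide, at -0.17 ± 0.11. Without 1 replicate, Ins1 ranged from -0.020 to 0.054, Ins2 from -0.072 to 0.0090, Gcg from -0.16 to 0.15, Ghrl from -0.20 to -0.090 and Pyy from -0.11 to -0.024. Ppy varied between arrays, at -0.42, -0.28, -0.30 and 0.31 on arrays 1 to 4, and passed without replicate 4 at -0.33 (adjusted p = 0.028). With median centring 6 of the 7 genes passed as higher, with Ins2, Ghrl and Pyy at 0.57, 0.31 and 0.35. The list median was -0.025 (camera adjusted p = 0.601).

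Among 20 endocrine transcription factors, Neurog3, which specifies endocrine progenitors, was higher at 0.33 ± 0.069 (adjusted p = 0.060 to 0.081 without replicate 2, 3 or 4), and 0 fell, with the same counts adjusted over the list alone (median 0.032, camera adjusted p = 0.736). Of 24 genes of beta cell function, 5 were lower and 1 higher, also when adjusted over the list alone. Slc2a2, a glucose transporter, fell by 0.33 ± 0.055. G6pc2, an islet glucose-6-phosphatase, was at -0.37 ± 0.072 (adjusted p = 0.053 without replicate 3) and Slc30a8, the granule zinc transporter, at -0.28 ± 0.061 (adjusted p = 0.071 to 0.092 without replicate 1, 3 or 4). With median centring Slc2a2, G6pc2 and Slc30a8 did not pass (-0.13, -0.046 and -0.072). The granins Chga and Chgb were lower at -0.24 ± 0.060 (adjusted p = 0.071 to 0.121 without replicate 1, 3 or 4) and -0.31 ± 0.082 (adjusted p = 0.095 to 0.135 without replicate 1, 2 or 3) with loess but at 0.23 and 0.045 with median centring, and Trpm5 was higher at 0.19 ± 0.046 (adjusted p = 0.078 to 0.131 without replicate 1, 3 or 4). The median of the beta cell list was -0.099 (camera adjusted p = 0.029; adjusted p = 0.761 with an estimated correlation), and 0.16 with median centring, or -0.093 relative to the median of all genes. Without replicate 1 or 3 the list did not pass (camera adjusted p = 0.107 and 0.131), and its median without replicate 3 was -0.036.

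**Figure D2:**
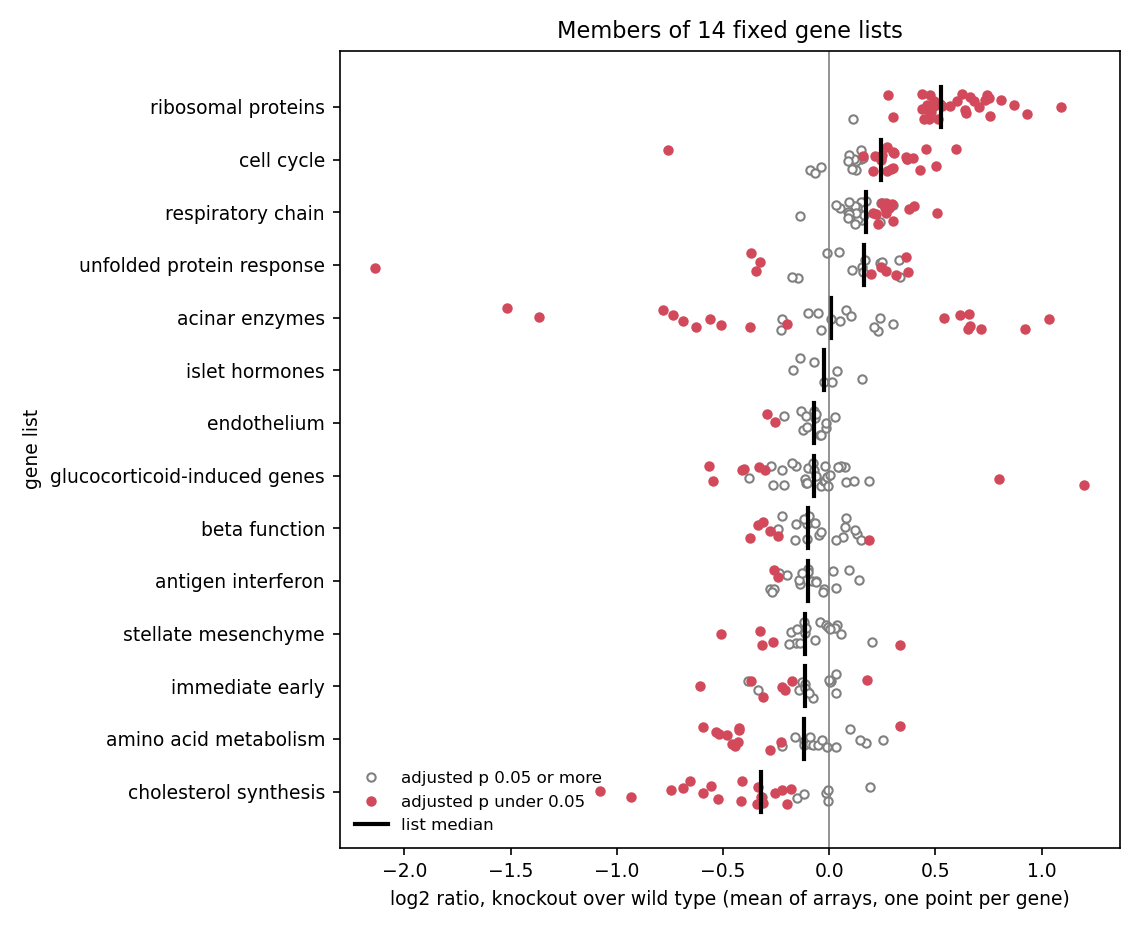
Log2 ratios of knockout over wild type (x axis, mean over arrays) of the measured members of 14 gene lists (y axis), with 1 point per gene, filled where the adjusted p was under 0.05, and a black line at the list median. Medians run from -0.32 for cholesterol synthesis to 0.53 for ribosomal proteins, while with median centring in place of loess 7 of the 8 lists called lower had medians above 0. Of these 8 medians, 7 lay below the median of all genes.

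Of 21 immediate early and stress response genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone). Klf6, a transcription factor, fell by 0.61 ± 0.055, and Hspa1b, an inducible heat shock protein, was lower at -0.31 ± 0.057 with loess but at 0.21 with median centring, and its other tested probe gave -0.019 with loess. Ier2 was the member that was higher, at 0.18 ± 0.045 (adjusted p = 0.075 to 0.147 without replicate 1, 2, 3 or 4). The median of these genes was -0.11 (camera adjusted p = 1.5e-04; adjusted p = 0.341 with an estimated correlation), and -0.072 with median centring, or -0.33 relative to the median of all genes.

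Of 22 fibroblast, stellate and smooth muscle markers, 4 were lower and 1 higher (5 and 1 adjusted over the list alone). Fbn1, fibrillin, fell by 0.51 ± 0.070, but did not pass with median centring (-0.13). Cnn1 (-0.33 ± 0.048), Col5a1 (-0.31 ± 0.052) and Col6a1 (-0.27 ± 0.067, adjusted p = 0.060 to 0.106 without replicate 1, 2, 3 or 4) were lower with loess but at 0.12, 0.20 and 0.13 with median centring, and Pdgfrb was higher at 0.33 ± 0.069 (adjusted p = 0.059 to 0.077 without replicate 2 or 4). The median of these markers was -0.11 (camera adjusted p = 0.0049, or 0.738 with an estimated correlation). With median centring it was 0.36, or 0.11 relative to the median of all genes, so the direction turned. The list then did not pass (camera adjusted p = 0.133). Median centring also leaves a trend with brightness in place, so no opposite change is read from this. Without replicate 2 the median with loess was -0.067 (camera adjusted p = 0.047).

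Of 15 endothelial markers, Tek (-0.29 ± 0.065, adjusted p = 0.080 to 0.090 without replicate 3 or 4) and Flt1 (-0.26 ± 0.061, adjusted p = 0.103 to 0.114 without replicate 1, 3 or 4) were lower and 0 were higher (3 and 0 adjusted over the list alone), and Flt1 was at 0.014 with median centring and -0.10 on its other tested probe. The median was -0.072 (camera adjusted p = 0.0030, or 0.341 with an estimated correlation). With median centring it was 0.25, or -0.0056 relative to the median of all genes. The direction of the test then turned, but the list did not pass (camera adjusted p = 0.96). Of 21 interferon and antigen presentation genes, B2m (-0.26 ± 0.054, adjusted p = 0.058 to 0.067 without replicate 1 or 3) and H2-Aa (-0.24 ± 0.066, adjusted p = 0.103 to 0.127 without replicate 1, 2 or 4) were lower and 0 were higher (1 and 0 adjusted over the list alone), but they were at 0.12 and 0.012 with median centring. The other tested probe of H2-Aa gave 0.12. Their list had a median of -0.10 (camera adjusted p = 0.011; adjusted p = 0.761 with an estimated correlation), and 0.030 with median centring, or -0.23 relative to the median of all genes, and did not pass without replicate 2 (median -0.043, camera adjusted p = 0.267).

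Markers of liver and red cells varied between arrays. Alb, serum albumin, was at 4.13, 2.70, -3.52 and 1.44 on arrays 1 to 4 and Ahsg, fetuin, at 4.09, 2.69, -2.93 and 1.44, so both were higher in knockout on 3 arrays and lower on 1. Over 15 liver markers the array medians were 0.98, 0.39, -0.45 and 0.13 (median 0.25, camera adjusted p = 0.334), and Vtn rose while 0 fell, also when adjusted over the list alone. Without replicate 3 the liver list passed, with a median of 0.66 (camera adjusted p = 2.6e-05), and Alb and Ahsg passed at 2.76 and 2.74. Without replicate 1 the liver median was 0.052 (camera adjusted p = 0.97), with Alb at 0.21 and Ahsg at 0.40. Serpina6, Gc and Vtn, which liver also makes, were positive on all 4 arrays, as the rule for the largest changes required. Over 14 red cell markers the array medians were 0.44, 0.076, -0.45 and 0.20 (median 0.23, camera adjusted p = 0.067), and without replicate 3 the list passed (0.27, camera adjusted p = 8.4e-05). Their median was 0.11 without replicate 1 and 0.13 without replicate 4 (camera adjusted p = 0.419 and 0.199). Of these, Hemgn was higher at 0.23 ± 0.048 (adjusted p = 0.075 to 0.082 without replicate 3 or 4) and 0 were lower, also when adjusted over the list alone, though other tested probes of Hemgn gave -0.071 and 0.13.

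Without replicates 1 and 3, whose ratios of liver markers lay farthest apart, 685 genes passed (450 higher and 235 lower), 603 of them among the 2260. The lists of cholesterol synthesis (-0.25), ribosomal proteins (0.61), cell cycle (0.22) and respiratory chain (0.27) then still passed, and the glucocorticoid-induced and beta cell lists did not (camera adjusted p = 0.051 and 0.876). Lists that then passed, though not over 4 arrays, were red cell (0.21), liver (0.26), unfolded protein response (0.25), myeloid (-0.17), lymphoid (-0.085), and mesothelial (-0.13), with camera adjusted p between 1.9e-04 and 0.030.

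**Figure D3:**
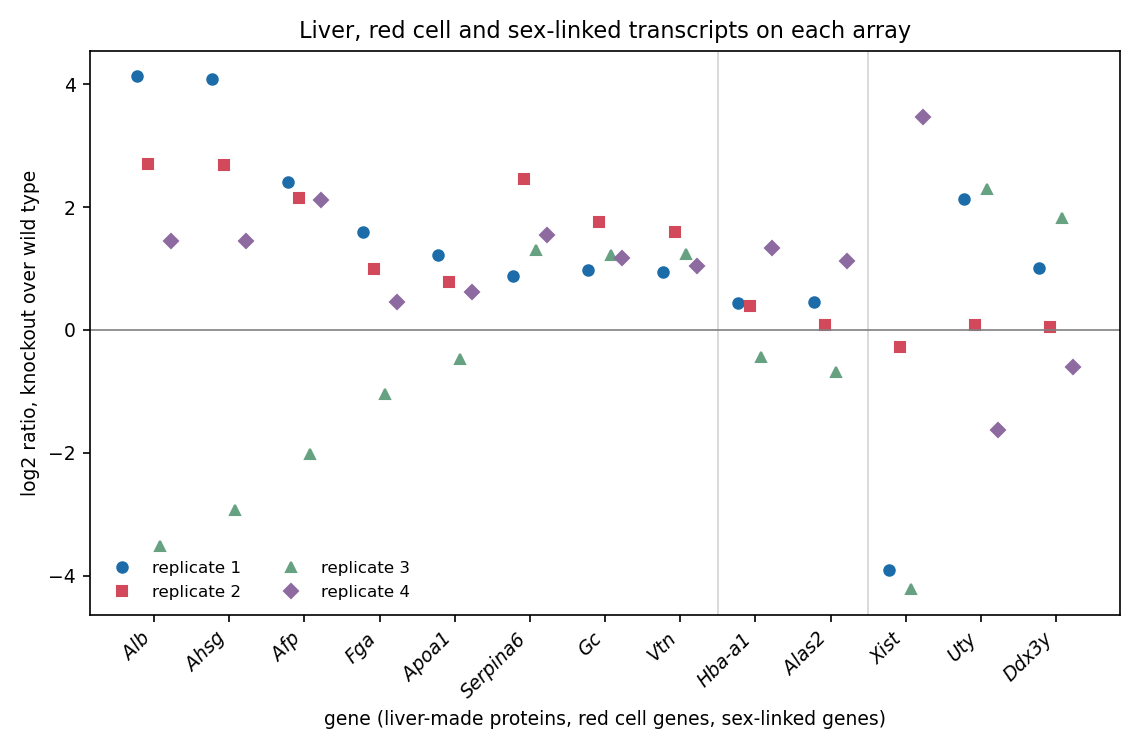
Log2 ratios of knockout over wild type (y axis) of 13 genes (x axis), with 1 point per array. Alb runs from -3.52 on array 3 to 4.13 on array 1. Serpina6, Gc and Vtn lie above 0 on all 4 arrays, which the rule for choosing them required. Xist lies on the other side of 0 from the Y-linked genes Uty and Ddx3y on each array.

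Sex-linked genes also varied between arrays. Xist, expressed from the inactive X of females, was at -3.91, -0.28, -4.22 and 3.46 on arrays 1 to 4, and the Y-linked Uty at 2.13, 0.078, 2.30 and -1.64. Xist was thus lower and Uty higher in the knockout extract on arrays 1 and 3, and the other way round on array 4, so the paired extracts of these 3 arrays differed in female and male transcripts. The sex of the embryos is not given in the sources used here. Ddx3y (0.57 ± 0.34), Eif2s3y (0.65 ± 0.45), Uty (0.72 ± 0.59), Kdm5d (0.089 ± 0.27) and Xist (-1.24 ± 1.13) did not pass in limma over the 4 arrays, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05. Without replicate 4, Eif2s3y passed at 1.26 (adjusted p = 0.044). Without 1 replicate, Ddx3y ranged from 0.15 to 0.96 and Kdm5d from -0.16 to 0.38, and Uty was at 1.501 without replicate 4. Uty was at 0.11 without replicate 1 and 0.10 without replicate 3, where another probe represented the gene. Over the 4 arrays its other tested probe gave 0.32. The median of the 5 genes was 0.57 (camera adjusted p = 0.694). In a count chosen after the values were seen, 42 other genes had the array order of Xist, with array 4 over 1 log2 unit above arrays 1 and 3 and array 2 between them, and 4 had the opposite order, the Y-linked genes. Of the genes with the order of Xist, Tmed11 was the one that passed the threshold, at -2.71, -2.30, -2.75 and -1.43 on arrays 1 to 4. Whether such probes also bind Xist was not tested.

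The remaining lists did not pass the set test. Of 20 duct markers, the keratin genes Krt18 (0.30 ± 0.045) and Krt8 (0.21 ± 0.052, adjusted p = 0.067 to 0.133 without replicate 1, 2, 3 or 4) were higher and 0 lower (median 0.082, camera adjusted p = 0.168). Of 21 myeloid markers, C1qa, a complement component of macrophages, rose by 0.48 ± 0.065 and Camp, of neutrophil granules, fell by 0.81 ± 0.10 (median -0.021, mean 0.0078, test downwards, camera adjusted p = 0.447), with array medians of 0.12, -0.41, 0.19 and -0.060 and a median of 0.095 without replicate 2. Of 13 adrenal markers, Ddc, which makes dopamine and serotonin, rose by 0.89 ± 0.063 and Chga was lower (median -0.035, mean 0.025, test downwards, camera adjusted p = 0.511). Of 24 glycolysis and hypoxia genes, Car9 rose by 0.58 ± 0.050 and Tpi1 was higher at 0.26 ± 0.071 (adjusted p = 0.12 to 0.147 without replicate 2, 3 or 4), while Egln3 was lower at -0.64 ± 0.14 (adjusted p = 0.061 to 0.088 without replicate 1, 3 or 4). Hk1, hexokinase 1, was lower at -0.23 ± 0.048 (adjusted p = 0.076 to 0.092 without replicate 1 or 4) but at 0.33 with median centring, and its other tested probes gave 0.063, -0.057 and 0.031. The glycolysis list had 4 higher and 4 lower members adjusted over the list alone (median -0.024, camera adjusted p = 0.694).

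Of 12 adipose markers, Dgat2, which makes triglycerides, fell by 0.29 ± 0.047 but did not pass with median centring (-0.0013). Lpl was lower at -0.26 ± 0.070 (adjusted p = 0.0502 to 0.123 without replicate 1, 2, 3 or 4) and Plin1 higher at 0.19 ± 0.053 (adjusted p = 0.062 to 0.179 without replicate 1, 2, 3 or 4), and Lpl did not pass with median centring (-0.085). The adipose list had a median of -0.044 (camera adjusted p = 0.214). Of 16 skeletal muscle markers, Ckm was higher at 0.26 ± 0.066 (adjusted p = 0.097 to 0.144 without replicate 2, 3 or 4), and Myh8 was lower at -0.23 ± 0.047 (adjusted p = 0.068 to 0.091 without replicate 1, 3 or 4) but at 0.32 with median centring (median 0.0032, mean -0.055, test downwards, camera adjusted p = 0.632). Of 16 lymphoid markers, Cxcr5 was lower at -0.25 ± 0.059 (adjusted p = 0.062 to 0.107 without replicate 2, 3 or 4) but at 0.17 with median centring (median -0.028, camera adjusted p = 0.214). None of 17 gut and stomach markers passed in limma, and 3 had an unadjusted p under 0.05 (median -0.0077, mean 0.016, test downwards, camera adjusted p = 0.80). None of 19 neural markers passed either, with 2 at an unadjusted p under 0.05 (median 0.0098, mean 0.011, test downwards, camera adjusted p = 0.837). Of 9 mesothelial markers 0 passed, 4 had an unadjusted p under 0.05 and 3 were lower adjusted over the list alone (median -0.15, camera adjusted p = 0.111), and without replicate 3 the list passed (camera adjusted p = 0.015), while without replicate 2 its median was -0.024 (camera adjusted p = 0.344). Adjusted over the list alone, 2 adrenal markers were lower, and the counts for the duct, myeloid, adipose, muscle, lymphoid, gut and neural lists were the same as over all genes.

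The counts within lists also moved with the scaling. Of all 15523 genes, 9471 passed as higher and 2450 as lower with median centring. The counts below are not corrected for that shift, so a list with mostly higher members need not differ from other genes. With median centring 33 respiratory chain genes rose and 0 fell, 31 cell cycle genes rose and 2 fell, and 34 ribosomal protein genes rose and 0 fell. In the other lists the members past the threshold as higher and as lower were 16 and 0 for duct, 9 and 3 for myeloid, 8 and 7 for lymphoid, 7 and 5 for adrenal, 5 and 4 for adipose, 12 and 1 for muscle, 6 and 6 for gut, 12 and 5 for neural and 3 and 3 for mesothelial markers. They were 9 and 5 for cholesterol, 17 and 6 for glucocorticoid-induced, 9 and 9 for immediate early, 12 and 1 for beta cell, 13 and 0 for endocrine regulator, 10 and 1 for acinar regulator, 15 and 2 for fatty acid oxidation and 20 and 2 for glycolysis genes, and 18 and 0 for stellate, 10 and 2 for endothelial, 7 and 4 for interferon, 8 and 0 for liver, 8 and 1 for red cell and 7 and 3 for steroid receptor genes. With the processed signals of Feature Extraction, Flt1, Lpl, Plin1, Ckm, Egln3, Tpi1, B2m, H2-Aa, Ier2, Mt1, Atf4, Cpb1, Col6a1, Hadhb and Chgb did not pass, with limma adjusted p from 0.054 (Lpl) to 0.097 (Ckm). With the mean of all probes of a gene, Hemgn, Hk1 and H2-Aa did not pass (0.099, -0.048 and -0.061). Mt1 and Egln3 did not pass with eBayes trend and robust (limma adjusted p = 0.211 and 0.092).

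The medians of several lists that did not pass moved by over 1.5 times when 1 replicate was left out. They ranged from -0.044 to 0.12 for acinar products, from 0.072 to 0.12 for acinar regulators, from -0.096 to 0.0090 for islet hormones, from -0.016 to 0.022 for endocrine regulators, from -0.054 to -0.011 for lymphoid markers, from -0.0073 to 0.0094 for gut markers, from -0.064 to 0.0065 for adrenal markers, from -0.00078 to 0.040 for neural markers and from -0.026 to 0.0079 for muscle markers. They ranged from -0.032 to -0.011 for steroid synthesis, from 0.043 to 0.085 for steroid receptors, from 0.058 to 0.099 for fatty acid oxidation, from -0.067 to 0.027 for glycolysis and from -0.087 to 0.095 for myeloid markers.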

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

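Among 203 named genes and list medians with values on all 4 arrays, 13 had 1 array far from the other 3, where chance alone gives about 1 in 20. The value on that array is given with the median of the others. Array 1 stood apart for Pnliprp1 (0.51 against 1.06), Muc1 (-0.084 against 0.29), Hemgn (0.12 against 0.27), Tap1 (0.38 against 0.062) and Gamt (0.14 against 0.39). Array 2 stood apart for Nup214 (-1.52 against -0.83), Krt18 (0.39 against 0.27), Sox17 (-0.043 against -0.15) and Acaa2 (0.54 against 0.31). Array 3 stood apart for Sst (-0.030 against 0.21), Krt8 (0.36 against 0.16) and C1qa (0.71 against 0.41), and array 4 for Stat2 (0.045 against -0.21).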

How the results depend on the processing

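Leaving out spots marked as population outliers, and leaving out replicates 1 and 3 together, were chosen after seeing the data. The count of genes past the threshold stayed within 1.5 times of 2260 without background correction, with processed signals, with the log ratio column, with scaling, with no or a strict filter, with the mean of probes, with trend and robust, with array weights and without population outliers (1765 to 2502). Leaving out 1 replicate gave 963 to 1627 genes, 614 to 995 higher and 349 to 632 lower, and leaving out replicates 1 and 3 gave 685 (450 higher, 235 lower), with fewer arrays in each fit. Every probe on its own gave 3501 probes, 1341 of them lower, among more features tested. Without the array as a block, the pairing of extracts was ignored and 91 genes passed (65 higher, 26 lower). Median centring gave 11921 genes (9471 higher, 2450 lower). It leaves a trend with brightness in place, with a median log2 ratio of -0.28 over the dimmest 20% of genes and 0.49 over the brightest, against 0.018 and 0.0029 with loess. Relative to the median of all genes (0.26), 2006 of the 2260 called genes had the sign they had with loess, as had 103 of the 107 called genes that were named. Cyp11a1 on its brighter probe stayed between -0.23 and -0.082 and short of the threshold under the 18 settings run. Of the 107 named genes past the threshold, 15 fell short of it when processed signals were used, 8 with trend and robust, and 91 without the array as a block. Dim transcripts, below the filter on signal over background, were left out of the main test. The setting with no filter included them, with 17138 genes run and 2229 past the threshold.

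With median centring the lists of ribosomal proteins, cell cycle and respiratory chain passed. Signs of single genes are read here against 0, while the median of all genes was then 0.26. No longer past the threshold were the medians of beta cell function (0.16), glucocorticoid-induced (0.14), cholesterol synthesis (0.018), immediate early (-0.072), amino acid (0.091) and interferon genes (0.030). Stellate (0.36) and endothelial markers (0.25) did not pass either (camera adjusted p = 0.133 and 0.96), and the direction of their test turned with median centring. Named genes whose sign it turned included Ghrl (0.31), Pyy (0.35), Ins2 (0.57), Epcam (0.41), Cnn1 (0.12), Col5a1 (0.20), Flt1 (0.014), Cdh5 (0.21), Mpo (0.41), Cxcr5 (0.17), Cd4 (0.30), Cblif (-0.24), Chga (0.23), Ret (-0.25), Ncam1 (0.32), Fabp4 (0.51), Myh8 (0.32), Des (0.26), Hsd11b1 (0.079), Cd36 (0.069), Hk1 (0.33), Hspa1b (0.21), B2m (0.12), H2-Aa (0.012), Tap1 (-0.24), Atf4 (0.10), Tsc22d3 (0.28), Try5 (0.052), Col6a1 (0.13) and Chgb (0.045). With an estimated correlation 0 lists passed (4 at an unadjusted p under 0.05), with adjusted p of 0.341 for endothelial, glucocorticoid-induced, cholesterol, cell cycle, immediate early and amino acid genes, 0.391 for ribosomal proteins, 0.738 for stellate and respiratory chain genes and 0.761 for beta cell and interferon genes. With fry 6 passed, and adjusted p was 0.427 for beta cell, 0.285 for stellate, 0.069 for endothelial, 0.091 for respiratory chain and 0.472 for interferon genes. Without 1 replicate the beta cell median was -0.13 to -0.036, the interferon median -0.14 to -0.043, and Sugct -1.25 to 0.075, the last from its other probe. Without replicates 1 and 3 the beta cell (0.018) and glucocorticoid-induced medians (-0.026) no longer passed, and Kdm5d turned to -0.63. The cause of the other changes was not tested.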

Other observations

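The tests on other probes of the same genes, and the test of Serpina6, Gc and Vtn against the liver score, were chosen only after the result was seen. There are 8 ways of turning the signs of the 4 arrays, too few for a share under 0.05. The real signs gave 2260 genes past the threshold, and the highest of the other ways gave 1.

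Ribosomal protein genes had array medians of 0.37, 0.70, 0.53 and 0.62. Their median lay at percentile 100 of 10000 random lists of genes of matched brightness (highest random median 0.10). Other genes of that brightness thus did not share the shift after loess. Loess itself centres genes of similar brightness near 0, which brings the random medians near 0, so no wider conclusion on dye effects is drawn from this test. Of 13 other tested probes of 11 of these genes, 100% were above 0 (exact 95% interval 75.3% to 100%), which argues against dye effects of single probes. The interval treats the probes as independent, though they share the 4 arrays and some share a gene. A dye effect shared by whole transcripts cannot be told apart from genotype, since 0 of the 4 arrays held the knockout in green. A difference between the genotypes stays open as well, as a hypothesis.

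Cholesterol synthesis genes had array medians of -0.38, -0.21, -0.43 and -0.28. Of 20 other tested probes of 15 of these genes, 95% were below 0 (exact 95% interval 75.1% to 99.9%), which argues against dye effects of single probes. This interval, too, treats probes that share arrays and genes as independent. A line of the array medians on the liver score, the median log2 ratio of 14 liver markers on each array, gave -0.33 at a score of 0 (95% interval -0.61 to -0.053), which argues against liver RNA as the whole cause. A dye effect of whole transcripts cannot be told apart from genotype, with 0 arrays swapped. The array medians were lowest on arrays 1 and 3, where Xist was lower and Uty higher in knockout. Array 4, where these 2 genes went the other way, was below 0 as well (-0.28). A contribution of sex was not tested. The loss of Cyp11a1, whose substrate is cholesterol, may contribute, as a hypothesis that was not tested apart from the dye.

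Serpina6, Gc and Vtn were higher on each array, while the liver score was 1.03, 0.28, -0.46 and 0.12 and Alb ranged from -3.52 to 4.13. A line of their array medians on that score, which leaves out Vtn, gave 1.32 at a score of 0 (95% interval 0.38 to 2.26). The rule that named these genes required 1 sign on all 4 arrays, so a gene that turned negative with the liver score could not enter. This favours a value above 0 in advance, so no conclusion on liver RNA is drawn from the line. Of the 15 liver markers tested, 14 were well above background in both channels on all 4 arrays, and 1 (Tat) is also in the amino acid list. A dye effect cannot be told apart from genotype, with 0 arrays swapped and 1 tested probe for each of the 3 genes. A genotype difference in these genes stays open as a hypothesis, and liver RNA is not excluded.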
